A study of Arabidopsis thaliana with 4 samples.

How the data were processed

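Gene expression was measured in Arabidopsis thaliana seedlings of the Columbia background (Col-0) on one-colour NimbleGen expression arrays with Cy3-labelled total RNA. The 4 arrays fall into 2 groups of 2 biological replicates each, wild type and the jmj30-2 jmj32-1 double mutant. The deposited values are intensities, which the authors made with RMA, a method of array normalization and probe summary, per the submitters' processing notes. Each value carries a locus identifier and a transcript model number. The linear scale was read from the range of the values, since no label states it. The software that ran RMA, its version and the genome build behind the transcript models were not given in the sources used here. The lower quartile of the intensities lay between 4.29 and 4.43 and the upper quartile between 199.9 and 205 in the 4 arrays. The values hold no detection calls and no probe positions, so the precision of each comparison is limited by the number of arrays, and a feature in the dim part of the range may be a background level.

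The table holds 37118 features for 32627 loci, and 4550 of the features are second or later transcript models of a locus. Locus identifiers of 31993 loci were found in the RefSeq gene table of assembly TAIR10.1, which was used for names only, and 10597 loci had a gene symbol there. Intensities were converted to log2 with no pseudocount and no feature was filtered out. Each feature was tested with limma 3.58.1 (lmFit and eBayes, R 4.3.3) as jmj30 jmj32 minus wild type over all 4 arrays, and p-values were adjusted by Benjamini-Hochberg over the 37118 features with a threshold of 0.05. The fit had 2 residual degrees of freedom per feature plus 3.6 from the prior. An exact two-sided permutation test of 2 arrays against 2 cannot give a p below 0.333, so no such test is reported per gene. Features at least 2-fold apart in each of the 4 pairs of a mutant and a wild-type array were counted without a test, beside the same count for the other 2 ways of splitting the arrays.

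On data simulated with the real wild-type means and variances drawn from the fitted prior, with 200 of 37118 features changed, the limma step recovered none of the features changed by 1 on the log2 scale (0%), 9.6% of those changed by 2, 92% of those changed by 4 and 97.4% of those changed by 6, with 4.9 false calls per run. Many large changes ease the adjustment, so recovery is likely lower where few features differ, and the false calls stand beside many true ones. In the real arrays 4 features passed, and AT3G28899, with a difference of 4.12, did not. A simulated shift of the 26 clock genes by -0.5 on the log2 scale, with genes varying independently, was called by camera in 10 of 10 runs. The real clock genes had an estimated inter-gene correlation of 0.24, so these runs do not show how the test performs on them.

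Before the data were examined, 21 gene lists were fixed, with 343 distinct loci, of which 342 were measured. HSFB1 was not analysed here. The reference names of 331 of these loci held the symbol used here, and the other symbols are common names from general knowledge. A locus was represented by its brightest feature. Lists were tested with camera at the preset inter-gene correlation of 0.01, adjusted over the 21 lists, with camera at an estimated correlation and fry as further tests. The lists cover histone demethylases, the FLC clade, floral repressors, floral integrators, floral organ identity, the autonomous and FRIGIDA pathways, Polycomb and Trithorax, clock and photoperiod, growth at warm temperature, heat shock, gibberellin, salicylic acid, jasmonate, abscisic acid with cold and drought, photosynthesis, flavonoids, cell cycle, senescence, roots, seeds and reference genes.

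The genes named were also set before the data were examined. They are JMJ30, JMJ32, FLC, FT and SOC1; the 12 symbol-bearing genes with the largest fall and the 12 with the largest rise among features past the threshold, filled where too few passed with the smallest p among features at least 2-fold apart; and up to 4 members of each list with the smallest p. For the last part, the clock and warm-temperature lists and the flowering lists except the autonomous and FRIGIDA pathways each gave 4 members. Lists with a camera p under 0.05 also gave 4 each, and the others 2. This choice was made after the data were seen. Of several qualifying features of a locus, the brightest was named. Alternatives covered the replicate number as a block, other prior variances, renormalization, centring, filters on dim features, a fold threshold, an unmoderated test, a constant of 16 added before the log, 1 feature per locus and leaving out each array. The closing section also uses 24 genes of iron supply, a set chosen after the values of bHLH38, bHLH39, bHLH100, FRO3 and IRT1 were seen. Near-identical genes, such as bHLH38 with bHLH39, the SAUR19 to SAUR24 cluster and the LHCB1 and RBCS families, can share probe signal and are uncertain as single genes. Figures were drawn with matplotlib 3.10.9.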

Results

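Seedlings were grown on soil at 22°C in long days of 16 h light and 8 h dark, moved to 29°C at day 3 after germination and harvested at day 13. Wild type was compared with the jmj30 jmj32 double mutant, which carries the jmj30-2 and jmj32-1 alleles of a pair of related Jumonji C (JmjC) histone demethylase genes. Per the labels, the mutant flowered before wild type in comparable conditions. Each genotype had 2 biological replicates and 1 array per replicate. The question was which transcripts differ between the genotypes at elevated temperature. The median intensity was 35.7 and 32.2 in wild-type replicates 1 and 2, and 33.1 and 35.5 in mutant replicates 1 and 2. Log2 intensities correlated across features at r = 0.983 between the wild-type arrays, 0.979 between the mutant arrays and 0.976 to 0.986 between arrays of different genotype. Mutant replicate 1 had the lowest correlations with every other array (0.976, 0.976 and 0.979).

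The targeted gene JMJ30 (AT3G20810, also listed as JMJD5), which encodes a JmjC demethylase, fell in the mutant on all 3 of its features. Model 1 fell from 10.06 ± 0.02 to 3.62 ± 0.37 log2 units (mean ± SD, n = 2), which is 86.8-fold lower (log2 difference -6.44 ± 0.28 SE, limma adjusted p = 0.0157). Model 3 fell from 9.58 ± 0.23 to 1.67 ± 0.36 (log2 difference -7.91, limma adjusted p = 0.0131), and model 2 from 6.08 ± 0.16 to 1.51 ± 0.29 (log2 difference -4.57, limma adjusted p = 0.0431). The mutant means of models 2 and 3 lay below the lower quartile of the arrays. JMJ32 (AT3G45880), the other targeted gene, was dim in both genotypes, at 3.24 ± 0.02 in wild type and 2.49 ± 0.39 in the mutant. Its difference of -0.76 ± 0.28 SE did not pass the test (limma adjusted p = 0.964), and 36.9% of all features were dimmer. The difference of JMJ32 was -1.03 without mutant replicate 1, -0.48 without mutant replicate 2 and -0.23 with log2(value + 16). Both mutant arrays lay below both wild-type arrays for JMJ32. Where the probes lie relative to either mutation is not given in the sources used here. With either wild-type array left out, the limma adjusted p of JMJ30 model 1 was 0.69 (without replicate 1) or 0.676 (without replicate 2), while its difference stayed at -6.42 and -6.46. The call of model 3 was also lost in these fits, and that of model 2 in these fits, without mutant replicate 1 (limma adjusted p = 0.122), with quantile normalization repeated (limma adjusted p = 0.0719), without the dimmest 25% of features and with log2(value + 16) (difference -2.15, limma adjusted p = 0.244).

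**Figure D1:**
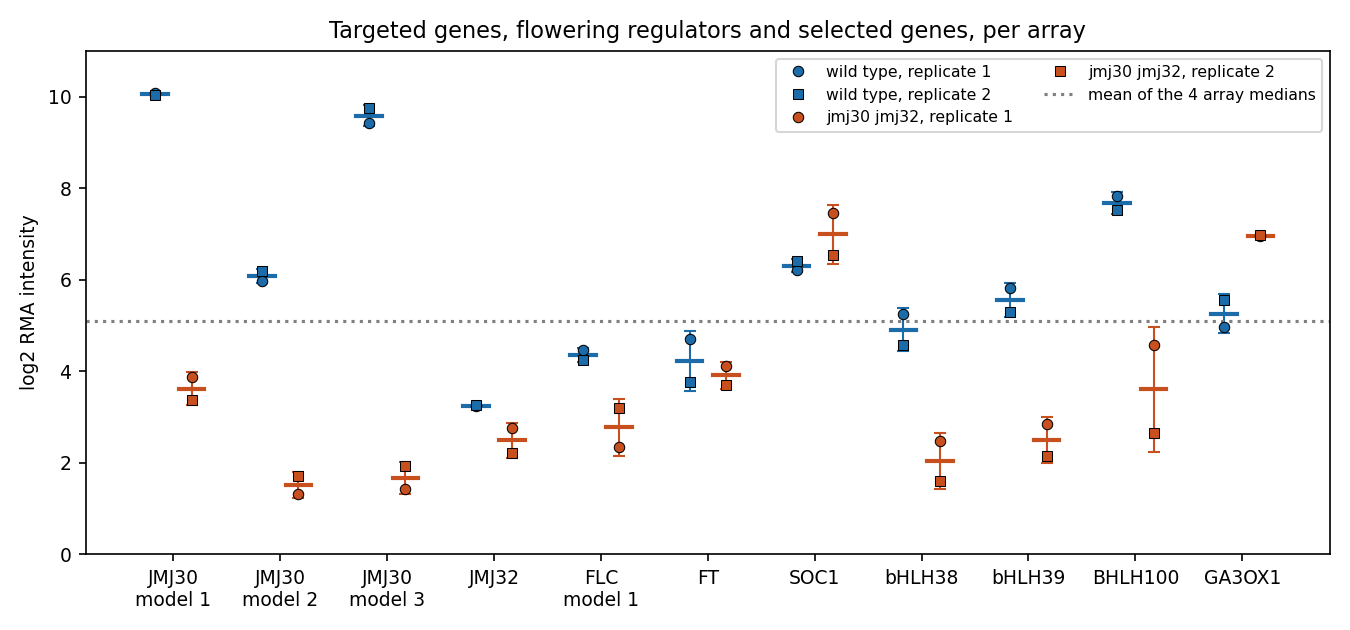
Log2 RMA intensity (y axis) of the targeted genes, 3 flowering regulators and 4 further named genes in each array; blue is wild type and orange jmj30 jmj32, circles are replicate 1 and squares replicate 2, bars give the mean ± SD, and the dotted line is the mean of the array medians. The 3 JMJ30 features lie far apart between genotypes, whereas FT overlaps.

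Across the array, 4 features passed the test, all lower in the mutant. They were the 3 features of JMJ30 and AT2G06845, which has no symbol in the reference table and is named because the count is small. AT2G06845 fell from 6.10 ± 0.08 to 1.88 ± 0.09 log2 units (n = 2, log2 difference -4.22 ± 0.23 SE, limma adjusted p = 0.042). By limma's adjusted p 0 were higher. With an intensity-dependent prior variance 8 were higher and 6 lower, and with each array centred on its median 1 was higher and 4 lower. An unmoderated two-sample test called 0 in either direction after adjustment. In limma 1003 features were higher and 763 lower at an unadjusted p under 0.05, together 1766 where chance gives 1856. The other splits of the 4 arrays gave 2006 and 1513 such features and no adjusted call. Features at least 2-fold higher in every pair of arrays numbered 59, and 51 were at least 2-fold lower, a total of 110 against 114 and 59 in the other splits. The 2 mutant arrays lay on one side of both wild-type arrays for 33.0% of features, where chance gives 33.3%. No feature passed with either wild-type array left out, 2 passed without mutant replicate 1 and 9 without mutant replicate 2, and the call of AT2G06845 was lost in each of these 4 fits. Its call was also lost without the dimmest 25% of features, with log2(value + 16) (difference -2.1, limma adjusted p = 0.202) and with 1 feature per locus (limma adjusted p = 0.0614).

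Of the flowering regulators FLC, FT and SOC1, the largest difference between genotypes was in FLC (FLOWERING LOCUS C, AT5G10140), a MADS-box repressor of flowering. Its brightest feature measured 4.35 ± 0.15 in wild type and 2.77 ± 0.61 in the mutant (log2 units, SD, n = 2), a 3-fold lower mean. The log2 difference was -1.59 ± 0.35 SE, and both mutant arrays lay below both wild-type arrays. It did not pass over all features (limma adjusted p = 0.964). Adjusted over the list alone, FLC passed for the 6 FLC-clade genes (limma adjusted p = 0.0283). It did not pass in the wider list of 16 floral repressors (limma adjusted p = 0.0753). An adjustment over 1 list alone does not allow for the 21 lists, so such a pass of FLC can arise by chance. The difference was -1.15 without mutant replicate 1, -2.02 without mutant replicate 2 and -0.66 with log2(value + 16). The other FLC features were near the lowest levels of the array, with 11.6% and 9.5% of features dimmer, and differed by 0.32 ± 0.28 and 0.49 ± 0.50 (SE), or 0.06 and 0.09 with log2(value + 16). With an array left out these 2 ran from 0.09 to 0.56 and from -0.10 to 1.09. FT (AT1G65480), which encodes the mobile flowering signal, measured 4.23 ± 0.66 in wild type and 3.91 ± 0.29 in the mutant (n = 2, log2 difference -0.32 ± 0.38 SE, limma adjusted p = 0.974), and its difference was 0.14 without wild-type replicate 1, -0.79 without wild-type replicate 2 and -0.18 with log2(value + 16). SOC1 (AT2G45660), a floral integrator downstream of FLC, measured 6.30 ± 0.14 and 6.99 ± 0.65 (n = 2, log2 difference 0.69 ± 0.36 SE, limma adjusted p = 0.964), and its difference was 0.23 without mutant replicate 1 and 1.15 without mutant replicate 2.

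The 5 flowering lists did not shift by the camera test over all features. Without the dimmest 50%, a filter that leaves out FLC, MAF4, MAF5, TFL1 and TOE3, the floral repressors were called (median 0.23, limma camera, adjusted p = 0.00378). Of the members left out, FLC, MAF4 and MAF5 had lower means in the mutant and TFL1 and TOE3 higher ones. This call therefore covers a different set of members. Only MAF2, MAF3 and FLM then remained of the FLC clade, with a median of 0.51. Of floral organ identity only SEP3 and SEP4 remained, with a median of -0.98. Values in brackets after a gene are the range of its difference with each array left out, given where this moved it by over 1.5 times. In the FLC clade, FLC was the 1 member of 6 to pass over the list alone. MAF3 differed by 0.51 (0.31 to 0.71), FLM by 0.59 (0.08 to 1.1) and MAF5 by -0.80 (-1.33 to -0.27) on the log2 scale, and the list median was -0.11 (limma camera, adjusted p = 0.458). The 16 floral repressors had a median of 0.13 (limma camera, adjusted p = 0.331), with TEM1, a repressor of FT, at 0.85 ± 0.24 SE and TOE1, an AP2-type repressor, at 0.54 ± 0.24 SE. Of the 17 floral integrators and promoters, 11 had a higher mean in the mutant and the median was 0.28 (limma camera, adjusted p = 0.209), or 0.09 without wild-type replicate 2. AGL71 differed by 0.69 (0.43 to 0.96), SPL15 by 0.51 (0.31 to 0.70) and SPL5 by 0.41, and none of the 17 passed over all features or over the list alone. The 13 floral organ identity genes had a median of 0.15 and a mean of -0.03 (limma camera, adjusted p = 0.445). In that list PISTILLATA (PI) differed by -1.04, AGAMOUS (AG) by 0.97 (0.63 to 1.31), CRC by 0.96 (0.51 to 1.42) and SEP1 by 0.56, and all 4 were dimmer than the median feature. The differences with log2(value + 16) were -0.18 for PI, 0.27 for AG, 0.19 for CRC, 0.28 for SEP1, -0.33 for MAF5 and 0.14 for AGL71. SEP3, a brighter member named after its values were seen, measured 7.90 ± 0.06 in wild type and 5.50 ± 3.20 in the mutant (n = 2, limma adjusted p = 0.964). Its mutant arrays were at 3.24 and 7.76, and its difference was -0.14 without mutant replicate 1 and -4.66 without mutant replicate 2 (limma adjusted p = 0.0499 in the latter). The 15 genes of the autonomous and FRIGIDA pathways, with FRL2 at -0.57 (-0.81 to -0.33) and FY at 0.47 (0.22 to 0.72), had a median of -0.09 (limma camera, adjusted p = 0.445).

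Among chromatin genes, JMJ20, another JmjC gene, measured 3.98 ± 0.25 in wild type and 5.28 ± 0.22 in the mutant (n = 2), a 2.46-fold higher mean. Its difference was 0.79 with log2(value + 16). It passed when adjusted over the list alone (limma adjusted p = 0.0345) but not over all features (limma adjusted p = 0.964). That list holds the mutated gene JMJ30, whose small p eases the adjustment for JMJ20, so this pass is not evidence on JMJ20 alone. An adjustment without JMJ30 was not made. Apart from JMJ30 and JMJ20, the other 18 of 20 histone demethylase genes did not pass over the list alone, and the list median was -0.07 (limma camera, adjusted p = 0.424). The 18 Polycomb and Trithorax genes had a median of 0.05 (limma camera, adjusted p = 0.704), with LHP1 at 0.36 and MEA at -0.42. The difference of MEA was -0.07 with log2(value + 16) or without mutant replicate 2, and -0.77 without mutant replicate 1.

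The 24 genes named by the size or p of their difference included several of the iron-deficiency response. JMJ30 was the 1 of these 24 that passed the test, so the others are given as values. BHLH100 (AT2G41240), bHLH39 (AT3G56980) and bHLH38 (AT3G56970) encode related transcription factors of that response. BHLH100 measured 7.67 ± 0.23 in wild type and 3.60 ± 1.36 in the mutant (n = 2), a 16.8-fold lower mean (limma adjusted p = 0.964). The log2 difference of BHLH100 was -5.03 without mutant replicate 1 and -3.11 without mutant replicate 2. Its limma adjusted p = 0.0407 when the prior variance was allowed to depend on intensity. bHLH39 measured 5.55 ± 0.37 and 2.50 ± 0.51 (n = 2, 8.32-fold lower mean, limma adjusted p = 0.664), and bHLH38 measured 4.91 ± 0.48 and 2.03 ± 0.61 (n = 2, limma adjusted p = 0.964), the latter below the lower quartile of the arrays. With log2(value + 16) the differences were -2.89 for BHLH100, -1.54 for bHLH39 and -1.2 for bHLH38. The sugar transporter gene SWEET10 had a 3.25-fold lower mean, the formin FH19 3.31-fold and the protein kinase CIPK20 3.38-fold. The cytochrome P450 gene CYP71A12 had a 2.11-fold lower mean. With log2(value + 16) these 4 differed by -0.74, -0.79, -0.86 and -0.49. The mutant means of the myosin gene XIE (1.96), the peptide gene CLE11 (1.43) and the cytochrome P450 gene CYP71B38 (1.72) lay below the lower quartile of the arrays, so no fold is given for them. Their wild-type means were 3.39, 2.83 and 2.85, and with log2(value + 16) they differed by -0.42, -0.30 and -0.27. FLC completes these 12 genes with lower means.

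On the side of higher means, GA3OX1 (AT1G15550), which catalyses the step that makes bioactive gibberellin, measured 5.26 ± 0.42 in wild type and 6.96 ± 0.01 in the mutant (n = 2), a 3.26-fold higher mean. It passed when adjusted over the list alone for the 17 gibberellin genes (limma adjusted p = 0.0224), not over all features (limma adjusted p = 0.964). The former adjustment again does not allow for the 21 lists, so this pass can arise by chance. SWAP70 model 2 had a 6.47-fold higher mean, and OVA1 model 2, RNEE/G model 3 and BRCC36A model 2 had 4.53-fold, 3.80-fold and 3.63-fold higher means, with limma adjusted p = 0.247, 0.589, 0.732 and 0.831. OVA1 encodes an organellar transfer RNA synthetase, RNEE/G a chloroplast ribonuclease and BRCC36A a DNA repair protein. With an intensity-dependent prior the limma adjusted p = 0.00951 for OVA1, 0.0222 for RNEE/G and 0.0407 for BRCC36A. The remaining features were DHS2 model 2 (3.87-fold), MAG1 model 2 (2.77-fold), RMR1 model 2 (2.68-fold), GER2 model 2 (2.66-fold), the transporter gene ABCG41 (2.57-fold), SLD5 model 2 (2.47-fold) and the 14-3-3 gene GRF1 model 2 (2.46-fold). Of these 12 features, 10 were second or later transcript models, against 0 of the 12 features with lower means. With log2(value + 16) the differences were 1.68 for SWAP70, 0.92 for DHS2, 0.57 for MAG1, 0.52 for GER2, 0.84 for ABCG41, 0.69 for GRF1 and 0.44 for SLD5. The first models of the same 10 loci differed by at most 0.42 on the log2 scale.

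Of the 21 lists, 5 shifted by limma's camera at the preset correlation, and none of their members passed over all features or over the list alone. All 14 anthocyanin and flavonoid genes had a higher mean in the mutant, with a list median of 0.91 on the log2 scale (limma camera, adjusted p = 7.71e-06, and 0.718 with an estimated correlation). CHS, the first enzyme of the pathway, differed by 0.92 ± 0.34 SE, FLS1 by 1.38 ± 0.47, F3H by 0.67 ± 0.28 and UF3GT by 2.24 ± 1.07. Of the 26 clock and photoperiod genes 20 had a lower mean, and the median was -0.36 (limma camera, adjusted p = 0.00322, and 0.718 with an estimated correlation). In that list LUX, of the evening complex, differed by -1.28 ± 0.49 SE, PRR7 by -0.85 ± 0.38, and the CO repressors CDF1 and CDF3 by -0.78 ± 0.27 and -1.09 ± 0.43. The 20 genes of growth at warm temperature had a median of -0.27 (limma camera, adjusted p = 0.0261, and 0.718 with an estimated correlation), with PIF4 at -1.33 ± 0.55, HFR1 at -1.96 ± 0.92 and the auxin synthesis genes YUC8 and YUC9 at -1.57 ± 0.52 and -1.27 ± 0.50 (SE). The 23 heat shock genes had a median of -0.49 (limma camera, adjusted p = 0.0188, and 0.718 with an estimated correlation), with MBF1C at -0.78, HSFA3 at -1.05, HSP21 at -0.66 and HSP17.6II at 1.04. Of the 23 salicylic acid defence genes 17 had a higher mean and 6 a lower one, among the latter PR1 at -0.84 ± 0.7 SE. The list median was 0.14 (limma camera, adjusted p = 0.0261, and 0.718 with an estimated correlation), with the regulator CBP60G at 1.12, WRKY70 at 0.69, NIMIN1 at 0.68 and WRKY38 at 0.51.

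All 5 calls were thus lost with an estimated correlation. It was 0.534 for flavonoids, 0.465 for heat shock and 0.376 for growth at warm temperature, against the preset 0.01. For the clock it was 0.24 and for salicylic acid defence 0.066. Without mutant replicate 1 the 5 medians were 0.17 for flavonoids, -0.08 for the clock, 0.05 for growth at warm temperature, -0.02 for heat shock and 0.10 for salicylic acid defence, and none of the 5 was called. Of the genes named in these lists, HFR1 then differed by -0.50, PIF4 by -0.51, YUC8 by -0.88, YUC9 by -0.54, LUX by -0.56, PRR7 by -0.35, CDF3 by -0.53, HSFA3 by -0.24, MBF1C by -0.32, F3H by 0.39, FLS1 by 0.71 and UF3GT by 0.51. Without mutant replicate 2 the medians were 1.53, -0.51, -1, -0.80 and 0.26, and all 5 were called. Leaving out wild-type replicate 1 left the flavonoid call alone, and leaving out wild-type replicate 2 left the flavonoid, clock and salicylic acid calls. CHS differed by 0.51 and HSP17.6II by 0.55 without wild-type replicate 1, HSP21 by -0.34 without wild-type replicate 2 and WRKY38 by 0.30 without mutant replicate 2. On the scale of log2(value + 16) the differences were 1.24 for UF3GT, 0.13 for F3H, -0.90 for YUC8, -0.56 for YUC9, 0.25 for HSP17.6II, -0.12 for HSP21, 0.40 for CBP60G, 0.27 for NIMIN1 and 0.12 for WRKY38.

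**Figure D2:**
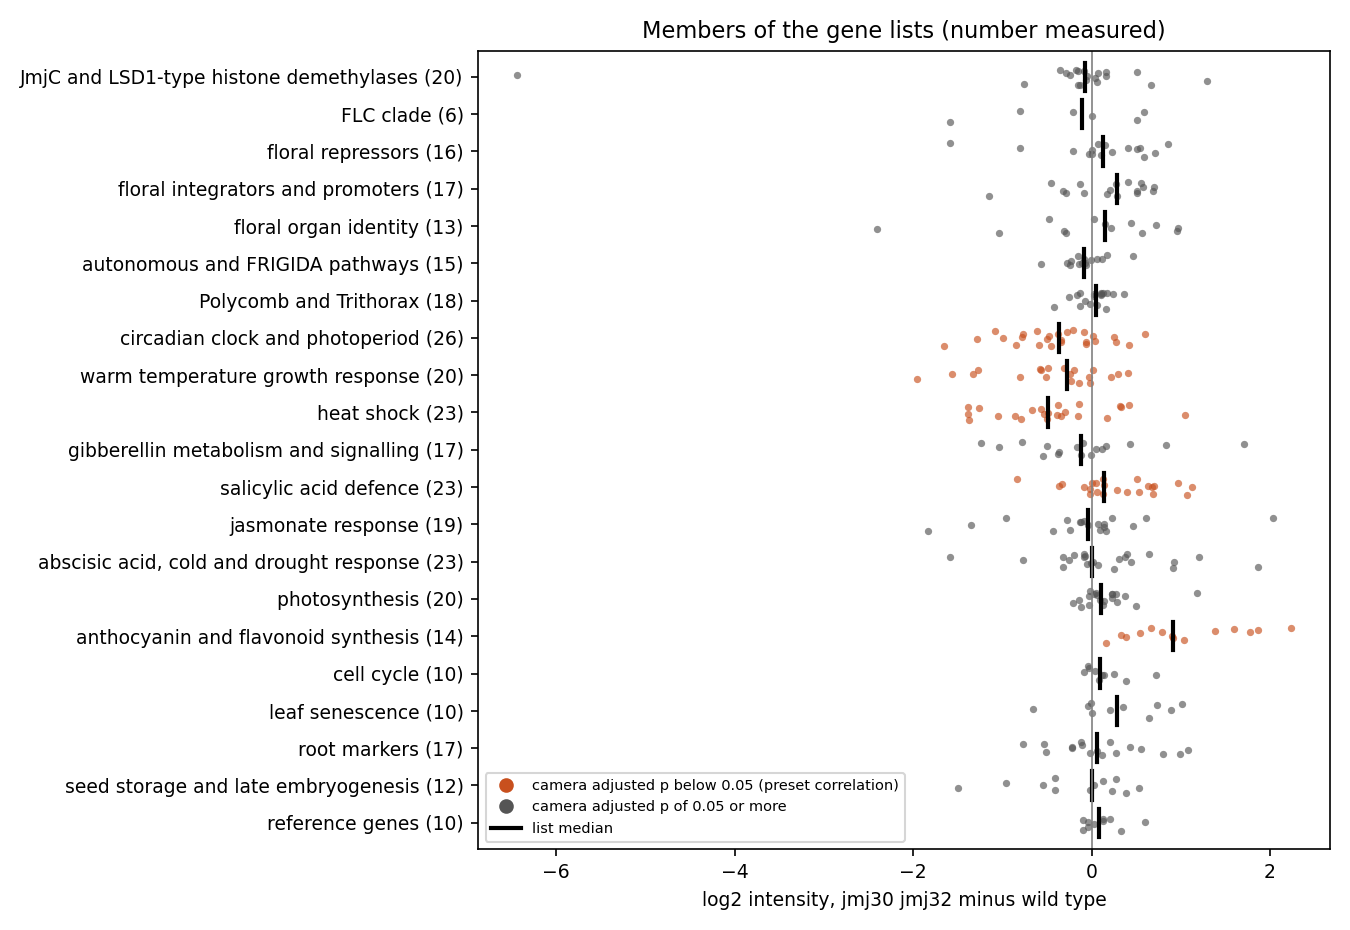
Log2 difference of intensity, jmj30 jmj32 minus wild type (x axis), for each measured member (points) of the 21 gene lists (y axis, number measured in brackets); black bars are list medians, and orange marks lists with a camera adjusted p under 0.05 at the preset correlation. The flavonoid list has its median at 0.91, the heat shock list at -0.49 and the clock list at -0.36.

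The other hormone, tissue and control lists did not shift over the 4 arrays, and brackets after a gene are again ranges with each array left out. The gibberellin list had a median of -0.12 (limma camera, adjusted p = 0.534), and GA2OX6, of gibberellin breakdown, differed by 0.83 (0.46 to 1.2). The jasmonate list had a median of -0.04 (limma camera, adjusted p = 0.649), with THI2.1 at -1.83 (-2.58 to -1.08) and JAZ7 at 0.46 (0.10 to 0.82). It was called without mutant replicate 2 (median -0.23, limma camera, adjusted p = 0.0253). The abscisic acid, cold and drought list had a median of 0.01, and -0.01 with each array centred on its median (limma camera, adjusted p = 0.424 before centring). In it NCED3, of abscisic acid synthesis, had a 2.30-fold higher mean (log2 difference 0.56 with log2(value + 16)) and RD20 differed by 0.91. Photosynthesis genes had a median of 0.11 (limma camera, adjusted p = 0.209), with LHCB1.1 at 1.18 (0.51 to 1.85) and RBCS1A at 0.50. Cell cycle genes had a median of 0.10 (limma camera, adjusted p = 0.424), with CYCB1;1 at 0.72 (0.06 to 1.37) and CDKB2;2 at 0.39 (0.06 to 0.71). Senescence genes had a median of 0.28 (limma camera, adjusted p = 0.317), with ORE1 at 1.01 (0.52 to 1.51) and ASN1 at -0.65 (-0.94 to -0.37). They were called without mutant replicate 1 (median 0.67, limma camera, adjusted p = 0.00257). Root markers had a median of 0.06 (limma camera, adjusted p = 0.458), with WOX5 at 0.80 and NRT2.1 at 1.08 (0.57 to 1.59). Seed storage and late embryogenesis genes had a median of 0 and a mean of -0.19 (limma camera, adjusted p = 0.424), with PER1 at -0.96 and OLEO1 at -1.49 (-2.28 to -0.71). Reference genes had a median of 0.08 (limma camera, adjusted p = 0.424), with GAPC1 at 0.60 and UBQ10 at 0.33 (0.03 to 0.62). In these lists log2(value + 16) gave differences of 0.32 for GA2OX6, -0.65 for THI2.1, 0.14 for JAZ7, 0.34 for LHCB1.1, 0.44 for ORE1, -0.24 for ASN1, 0.15 for WOX5, 0.28 for NRT2.1, -0.20 for PER1 and -0.38 for OLEO1.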

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

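Every setting below was chosen before the data were examined, and the causes of the changes were not tested unless a cause is given. The number of higher features was 8 with an intensity-dependent prior variance and 1 with the arrays centred on the median, against 0. The number of lower features was 0 with an unmoderated two-sample test, 2 without the dimmest 25% of features, 2 without the dimmest 50%, 2 with log2(value + 16) and 1 with 1 feature per locus, where the other JMJ30 features are left out by construction and AT2G06845 was no longer called (limma adjusted p = 0.0614). Leaving out each array in turn, with the lone array of a group assumed to vary like the other group, gave 0 to 9 lower features. Features at least 2-fold apart in every pair of arrays numbered 18 higher and 7 lower without the dimmest 50%, where fewer features are counted. With an array left out they numbered 253 to 694 higher and 159 to 867 lower, since fewer pairs of arrays must differ. A depth of signal near the lower end of the intensities limits many named genes, among them JMJ32, the FLC features, bHLH38, PI, AG, CRC, CBP60G and THI2.1. With log2(value + 16) the differences of 52 of 90 named features shrank by over 1.5 times, and with an array left out 43 of the 90 moved by as much.

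With the replicate number as a block, 1 feature was lower, JMJ30 model 3. JMJ30 model 1 differed by -6.44 (limma adjusted p = 0.0501), model 2 by -4.57 (limma adjusted p = 0.127) and AT2G06845 by -4.22 (limma adjusted p = 0.131). The study design speaks of independent sets of both genotypes, but no label says that a number marks a shared day or tray. The differences between replicates 1 and 2 of each genotype correlated at r = 0.051 across features, and at 0.092 in the brighter 50%. The split by replicate number gave 2006 features at an unadjusted p under 0.05, against 1766 for genotype. With only 2 pairs these values do not settle whether the numbers pair the samples, which were treated as sharing only a number.

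With all arrays, 601 differences of named genes kept direction and side of the threshold, 8 came to pass and 7 no longer did. With an array left out these were 346, 1 and 11, and 2 turned. The kept counts test little: only 4 features could lose a call, and other priors turn no direction. Without each array in turn, JMJ30 differed by -6.7 to -6.18, FT by -0.79 to 0.14 and FLC model 3 by -0.1 to 1.09 on the log2 scale. The number of shifted lists was 0 with camera at an estimated correlation, 0 with fry and 1 to 6 with an array left out, against 5. The FLC clade median was 0.51 and the floral organ identity median -0.98 without the dimmest 50% of features. Only MAF2, MAF3 and FLM of the first list, without FLC, and SEP3 and SEP4 of the second remain there. The median of the abscisic acid, cold and drought list was -0.01 with the arrays centred on the median. The median of the root markers was -0.02 without the dimmest 25% and -0.1 without the dimmest 50%. The floral repressors, less FLC, MAF4, MAF5, TFL1 and TOE3, passed without the dimmest 50% (median 0.23, limma camera, adjusted p = 0.00378). With the same filter 2 lists were no longer called: growth at warm temperature (median -0.23, limma camera, adjusted p = 0.0805) and salicylic acid defence (median 0.14, limma camera, adjusted p = 0.0555). Photosynthesis passed with an intensity-dependent prior (limma camera, adjusted p = 0.0328). With an array left out, list medians ran from -0.15 to 0.03 for histone demethylases, -0.18 to 0.43 for floral organ identity, -0.05 to 0.12 for Polycomb and Trithorax, 0.09 to 0.28 for floral integrators, 0 to 0.25 for floral repressors, -0.19 to -0.02 for the FLC clade, -0.21 to 0 for the autonomous pathway and -1 to 0.05 for growth at warm temperature. They ran from -0.36 to 0.32 for jasmonate, -0.09 to 0.16 for abscisic acid, -0.13 to 0.33 for the cell cycle, -0.04 to 0.67 for senescence, 0 to 0.22 for photosynthesis, -0.22 to -0.07 for gibberellin, -0.28 to 0.04 for seed genes, -0.08 to 0.15 for root markers and -0.03 to 0.23 for reference genes.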

Other observations

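The test of root tissue in this part was chosen after its result was seen; the gene set for iron was chosen after 5 of its members were seen. Iron-supply genes other than the bHLH genes named above were looked at as a group. FRO3, a ferric reductase gene, measured 8.70 ± 0.18 in wild type and 7.48 ± 0.38 in the mutant (log2 units, SD, n = 2, difference -1.21 ± 0.29 SE). Of 16 further iron-deficiency genes, 11 had a lower mean in the mutant and 4 had an unadjusted p under 0.05, all lower. These 4 were the peptide genes IMA3 (-1.98 ± 0.55 SE) and IMA2 (-0.96 ± 0.38), bHLH101 (-1.37 ± 0.44) and ORG1 (-0.74 ± 0.23). For bHLH101 the wild-type arrays were at 3.8 and 2.6, and its mutant mean of 1.83 lay below the lower quartile of the arrays. The mutant arrays of IMA3 were at 7.35 and 5.74. FIT, FRO2 and IRT1, which act in iron uptake by roots, differed by 0.27 ± 0.43, 0.24 ± 0.67 and 0.28 ± 0.33 (SE). The wild-type arrays were at 4.61 and 2.81 for FRO2, and only 12.7% of features were dimmer than IRT1. These 3 values therefore do not show a lack of change. The 3 ferritin genes, which store iron, had a median of 0.15. None of these genes passed over all features in limma (adjusted p = 0.964 or above).

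A hypothesis is that the iron-deficiency response as a whole was lower in the mutant. The sets tested were the 16 further genes, all 21 iron-deficiency genes and the 3 ferritin genes. The set of 21 holds the bHLH genes picked for their fall, and its small p eases the adjustment for the 16. The 16 genes had a median log2 difference of -0.37, short of the -0.5 set for this hypothesis beforehand (limma camera, adjusted p = 0.00219 over 3 sets, 0.435 with an estimated correlation). The median was -0.40 without mutant replicate 1 and -0.20 without mutant replicate 2 (limma camera, adjusted p = 5.03e-07 and 0.429), so the group shift cannot be told apart from variation between 2 arrays. Less root tissue as the whole cause of the lower bHLH genes would make genes of roots fall by about the mean bHLH difference of -3.34. The 3 root markers brighter than the median had a median difference of -0.1, with BGLU23 at -0.51 ± 0.41, SCR at 0.21 ± 0.25 and SHR at -0.10 ± 0.37 (SE). None of these 3 fell by as much. The other 14 of 17 markers were dimmer than the median, so it is unknown whether the 3 bright signals came from roots. These values therefore do not decide the question, and a loss of root tissue stays open. Genotype stays open as an untested source.

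Features of second or later transcript models made up 19% of the 1003 higher features and 6.6% of the 763 lower ones at an unadjusted p under 0.05, a gap of 12.5 points, against 12.3% of all features. Such features lay 0.053 ± 0.007 (bootstrap SE over loci) above first-model features of the same intensity, a shift that a bias by intensity alone would not give. This SE resamples loci within the same 4 arrays and holds no variation between arrays. A shift of the median also does not decide what made the gap at an unadjusted p under 0.05, so such a bias stays open for the gap. The other splits of the 4 arrays gave gaps of 5.7 and -6.5 points, and the largest of these, 6.5 in size, is over the limit set beforehand, so a technical difference between arrays that does not follow genotype cannot be told apart from genotype. No biological explanation was tested.

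Besides AT2G06845, single features without a symbol differed strongly and are named after their values were seen. AT3G28899 measured 2.92 ± 0.05 in wild type and 7.04 ± 0.35 in the mutant (n = 2, limma adjusted p = 0.0673, log2 difference 2.65 with log2(value + 16)), AT5G28335 4.50 ± 0.38 and 7.75 ± 0.12 (limma adjusted p = 0.247), and AT3G33076 4.01 ± 0.51 and 7.15 ± 0.16 (limma adjusted p = 0.465). With an intensity-dependent prior these passed (limma adjusted p = 0.0063, 0.0063 and 0.0185), and AT3G28899 also with the arrays centred on the median (limma adjusted p = 0.0421). A hypothesis is that genomic changes linked to the mutated genes account for such features. Within 100 loci of JMJ30 or JMJ32 in the order of the locus identifiers, 17 of 442 features had an unadjusted p under 0.05, or 3.85% (95% exact interval 2.26 to 6.09), against 4.76% of the rest (two-sided Fisher's exact test, p = 0.431). The limit set beforehand was wrong for these features, since 0 of the 4 named here lie in that window, and a share of features does not register a few strong ones. AT3G28899 and AT3G33076 lie between JMJ30 and JMJ32 in identifier order, whereas AT2G06845 and AT5G28335 carry identifiers of other chromosomes. Linkage to the mutated genes stays open for AT3G28899 and AT3G33076. No biological explanation was tested.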
